A study of Mus musculus with 9 samples.

How the data were processed

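RNA sequencing counts were analysed from RAW264.7 cells, a mouse macrophage-like line, transfected with either a mimic of the microRNA let-7c-5p or a negative control. The labels assign 4 libraries to the negative control and 5 to the let-7c-5p mimic and call them biological replicates. The deposited table holds whole-number read counts per gene, not normalized, one column per library. Per the submitters' processing notes, the authors used FastQC 0.11.9, HISAT2 2.1.0 (a spliced read aligner), HTSeq 0.11.2 (a read counter), R 4.3.2 and DESeq2 1.4.2. The genome build, the annotation, the strand setting of the counting and the treatment of reads with several matches are not given in the sources used here.

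The table analysed here holds 311 genes, far fewer than a macrophage transcriptome. The log2 ratio of the mean deposited counts, let-7c-5p mimic over control, was never between -0.98 and 0.98, so these genes had been chosen for a difference between the groups of about 2-fold or more. The rule of that choice is not given in the sources used here. This limits each number that follows. The column totals, 40655 to 83053 counts, are sums over a gene selection and not sequencing depths, which are unknown here. Fold changes are relative to the other genes of the table. A count of genes past the threshold does not estimate how many genes changed in the cells, and the p-values of genes already selected on the same libraries are too small as independent evidence. Of the genes, 167 had a mean under 10 counts, and 1 row had no gene symbol.

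Differential expression was tested with edgeR 4.0.16 in R 4.3.3: trimmed-mean (TMM) scaling, filterByExpr with its default minimum count of 10, and the two-sided quasi-likelihood test with group as the only term. P-values were adjusted by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were taken as the absolute fold change over the square root of the F statistic. Means and SDs are of the deposited counts, and whether groups overlap was also judged on these counts without scaling. Where a group was at 0 in each library, the fold was bounded with a floor of 3 counts over the group, which covers counting error only. No pair of replicates had identical or indistinguishable counts (chi-square per degree of freedom 2.51 to 85.3).

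The design, the alternatives and 33 gene lists were fixed before the data were examined. The genes named in the text follow a rule also fixed then. It takes the 10 called genes with the largest increase and the 10 with the largest decrease among genes with a mean of at least 50 counts and one direction in each leave-one-out fit. It adds the 2 list members with the largest called change in each direction per list, and 22 genes fixed by name, of which 2 were in the table. Lif, Csf2, Gas6, Cd36, Ifnb1, Cxcr4, Rpl17 and Muc19 were named in addition after their values were seen. Gene lists were to be tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01 where at least 5 members were tested. None of the lists reached 5, so that test could not be run as planned. Lists with at least 3 tested members were tested instead, with an estimated correlation beside it, a choice made after seeing the data. The fry test was run too and is not used, since it compares a list with no change and the genes had been selected for a change. Fisher's exact test of member direction against the rest of the table was added in the same way.

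Sequence features came from GENCODE mouse release M21, matched by gene ID, and no coordinates are given because the authors' build is unknown. Of the 311 IDs, 295 matched, including 96.6% of the tested genes. GC content and length were taken from the longest annotated transcript, and 3′ untranslated regions (UTRs) from the annotated coding ends. A let-7 seed site was an exact 7mer-m8 or 8mer match in the longest 3′ UTR. Near-identical genes were searched with blastn 2.17.0. Permutation tests of medians used 100000 resamples.

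Alternatives were DESeq2 size factors in edgeR, column totals, equal library sizes, no filter, DESeq2 1.42.0, limma-voom, an exact permutation test per gene, a fold minimum of 2, the replicate number as a block and leaving out each library. Scaling by housekeeping genes was planned and could not be run because 0 of the listed housekeeping genes were in the table. The edgeR step was tested on simulated data made from these libraries, in 10 simulations with 200 changed genes each and a mean of 163.3 genes tested. Among the simulated genes that passed the filter, it recovered 74.9% of 2-fold and 100% of 4-fold changes, called 3.49% of unchanged genes, and 1.94% of its calls were false. Changed genes below the filter were not counted in these shares. Those simulations did not include the selection of genes.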

Results

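Transcripts of RAW264.7 cells, a mouse macrophage-like line, were counted after transfection with a let-7c-5p mimic (5 libraries) or a negative control (4 libraries), to ask how let-7c-5p affects macrophage polarization and the functions that go with it. The counts covered 311 genes, each already differing about 2-fold or more between the groups. Their totals were 40655 to 50083 counts in the control libraries and 43241 to 83053 in the let-7c-5p libraries. These totals are sums over a gene selection, so fold changes are relative to the other genes of the table.

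Among single genes, Tnf, Cxcl2 and Ptgs2 were lower after let-7c-5p and Gpnmb was higher. Tnf (ENSMUSG00000024401), a central macrophage cytokine, had 9157 ± 1013 counts (SD, n = 4) in the control and 3800 ± 332 (SD, n = 5) with the mimic. Its log2 fold change was -1.33 ± 0.23 (SE, edgeR quasi-likelihood test, adjusted p = 2.8e-04). Cxcl2 (ENSMUSG00000058427), a chemokine that attracts neutrophils, went from 2769 ± 471 to 197 ± 148 counts, a log2 fold change of -3.96 ± 0.37. Ptgs2 (ENSMUSG00000032487), the inducible cyclooxygenase, went from 1008 ± 237 to 271 ± 78.9 counts, a log2 fold change of -1.95 ± 0.20. In contrast, Gpnmb (ENSMUSG00000029816), a lysosome-associated glycoprotein, rose from 3033 ± 88.8 to 7203 ± 855 counts, a log2 fold change of 1.16 ± 0.26.

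Of 28 listed inflammatory cytokines and chemokines, 6 were in the table and the mean of each was lower with the mimic. The 4 tested members, Tnf, Cxcl2, Csf3 and Lif, all fell. All 4 were also called when adjusted over the list alone, but 148 of the 149 tested genes of this selected table were called. Such counts of calls per list, here and below, are therefore no support for a list. Csf3 (ENSMUSG00000038067), the granulocyte colony-stimulating factor, fell by 3.56 on the log2 scale (SE 0.54), from 29 ± 16.1 to 2.6 ± 1.82 counts. Lif (ENSMUSG00000034394) fell by 2.28 (SE 0.45). The untested members were Il1b (ENSMUSG00000027398), with 14 ± 6.98 and 5 ± 1.41 counts in overlapping ranges, and Csf2 (ENSMUSG00000018916). Csf2 had a mean of 5.25 counts in the control and 0 in each of the 5 let-7c-5p libraries, at least 8.75-fold lower. Against the other genes of the table the list was lower by camera with a preset correlation (adjusted p = 0.021), a call lost with an estimated correlation (adjusted p = 0.12). By Fisher's exact test of direction against the rest of the table, 6 of 6 lower gave an adjusted p of 0.025. That test takes the genes as independent, while the correlation estimated for the tested members of this list was 0.33.

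Of 26 M1-type (pro-inflammatory) macrophage markers, 4 were in the table, and the 3 tested ones, Tnf, Ptgs2 and Il23a, all fell. The 3 of 3 calls when adjusted over the list alone again follow from the selection of genes. Il23a (ENSMUSG00000025383), a subunit of interleukin 23, fell by 1.97 on the log2 scale (SE 0.32). The list was lower by camera (adjusted p = 0.037), and the call was lost with an estimated correlation (adjusted p = 0.12) and by Fisher's exact test of direction (4 of 4 lower, adjusted p = 0.062). The correlation estimated for the tested M1 members was -0.014, below the preset 0.01, so correlation among them does not explain that loss. Tnf and Il1b stand in both lists, so the tests are not independent. Of 26 M2-type markers, 1 was in the table. This was Myc (ENSMUSG00000022346), a transcription factor that also stands among the 63 published let-7 targets, again as the only one present, and it fell by 1.09 (SE 0.25). Nos2, Il6, Arg1, Mrc1 and Il10 were not among the 311 genes and were not analysed here.

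**Figure D1:**
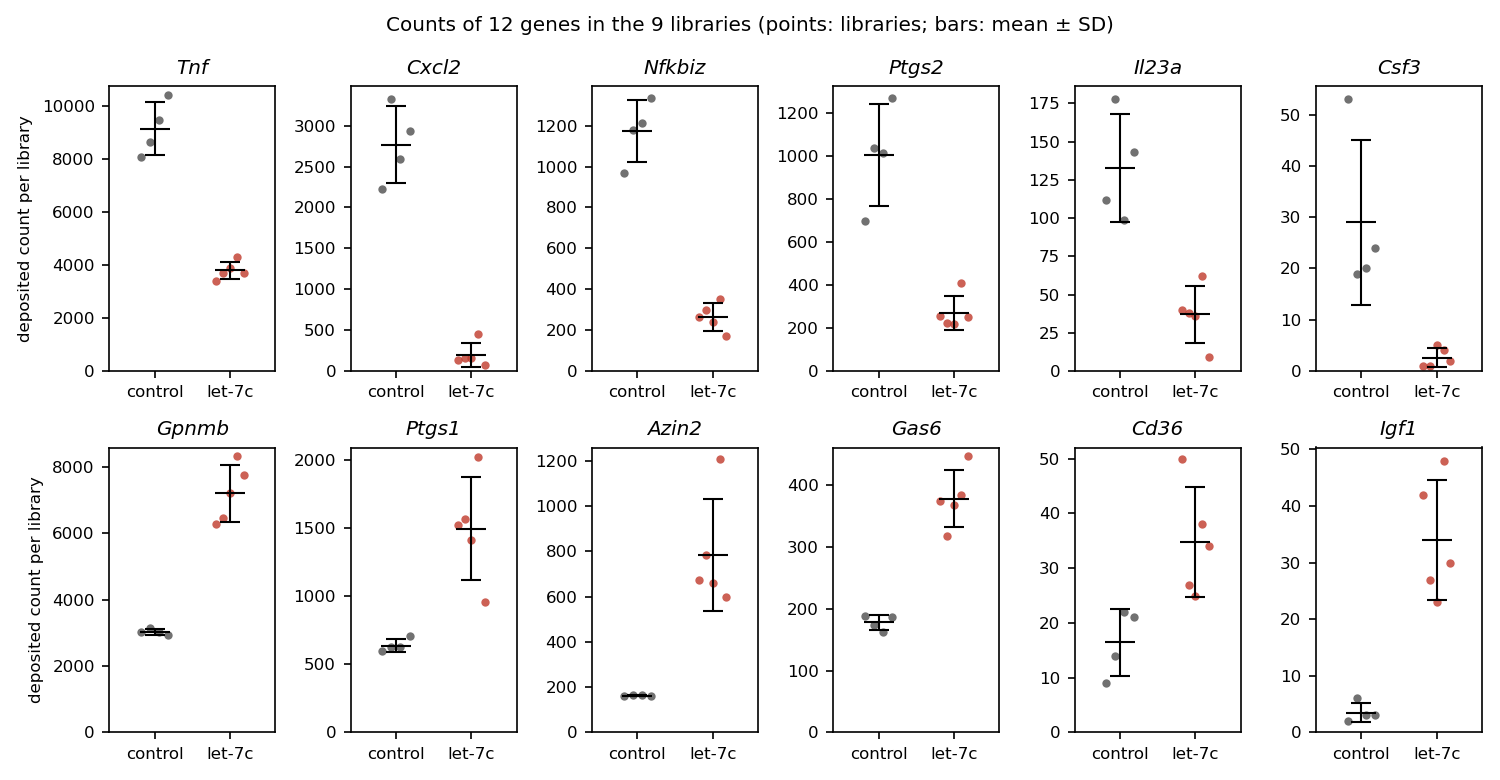
Deposited counts (vertical axis, reads per library, linear from 0) of 12 genes in the 4 control and 5 let-7c-5p libraries. Points are libraries and bars the mean ± SD; in each gene the groups do not overlap, for example Tnf with means of 9157 and 3800 and Gpnmb with means of 3033 and 7203.

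Of 41 NF-kappaB and toll-like receptor pathway genes, 2 were in the table and both fell. These were Nfkbiz (ENSMUSG00000035356), an inducible regulator of NF-kappaB, by 2.24 on the log2 scale (SE 0.19), and Tnfaip3 (ENSMUSG00000019850), an inhibitor of NF-kappaB signalling, by 1.13 (SE 0.17). Outside the lists, Lcn2 (ENSMUSG00000026822), an iron-siderophore binding protein, fell by 1.96 (SE 0.30) and Acod1 (ENSMUSG00000022126), which makes itaconate, by 1.22 (SE 0.23). Sh2d6 (ENSMUSG00000052631), Calcrl (ENSMUSG00000059588) and Pou2f2 (ENSMUSG00000008496) fell by 1.36, 1.34 and 1.33 (SE 0.23, 0.22 and 0.20). In Calcrl the groups overlapped, with 214 counts in control replicate 1 and 250 in let-7c-5p replicate 1. The immediate early gene Egr1 (ENSMUSG00000038418) fell by 1.10 (SE 0.22) and the protease gene Mmp9 (ENSMUSG00000017737), which also stands among the osteoclast markers, by 1.18 (SE 0.24). The p53 target genes Pmaip1 (ENSMUSG00000024521) and Eda2r (ENSMUSG00000034457) fell by 1.18 and 1.12 (SE 0.20 and 0.26). Adjusted p-values of these 11 genes lay at or below 0.0013.

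Of 38 listed genes of lysosomes and phagocytosis, 4 were in the table and these 4 rose: Gpnmb, Gas6, Itgax and Cd36. The 4 of 4 calls when adjusted over the list alone again follow from the selection of genes. Gas6 (ENSMUSG00000031451), which bridges apoptotic cells to phagocyte receptors, rose by 1.01 on the log2 scale (SE 0.22), Itgax (ENSMUSG00000030789), an integrin also listed as a dendritic cell marker, by 1.16 (SE 0.27), and Cd36 (ENSMUSG00000002944), a scavenger receptor, by 1.03 (SE 0.28). The list was higher by camera (adjusted p = 0.038), a call lost with an estimated correlation (adjusted p = 0.12) and by Fisher's exact test of direction (4 of 4 higher, adjusted p = 0.13). With column totals in place of TMM, Itgax and Cd36 kept a positive log2 fold change (0.80 and 0.62) but were no longer called.

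Igf1 (ENSMUSG00000020053), a growth factor, rose from 3.5 ± 1.73 to 34 ± 10.6 counts, a log2 fold change of 3.16 ± 0.37 (SE, adjusted p = 7.6e-06). Azin2 (ENSMUSG00000028789), an inhibitor of antizyme, rose from 163 ± 2.75 to 784 ± 246 counts, a log2 fold change of 2.15 ± 0.22. Col11a2 (ENSMUSG00000024330), Aldh1l1 (ENSMUSG00000030088), Hvcn1 (ENSMUSG00000064267) and Ier5l (ENSMUSG00000089762) rose by 1.65, 1.38, 1.31 and 1.23 (SE 0.37, 0.23, 0.21 and 0.37). Ptgs1 (ENSMUSG00000047250), the constitutive cyclooxygenase, rose by 1.12 (SE 0.20), opposite to Ptgs2, and Cbr2 (ENSMUSG00000025150) by 1.09 (SE 0.19). Vwf (ENSMUSG00000001930), listed as an endothelial marker, rose by 1.11 (SE 0.29), a call lost with column totals (0.82). Ifnb1 (ENSMUSG00000048806), with 17 counts over the let-7c-5p libraries and 1 over the control, and Cxcr4 (ENSMUSG00000045382), with 60 and 12, were below the filter and not tested. Of the 60 Cxcr4 counts, 28 came from let-7c-5p replicate 5, and the groups overlapped in this gene.

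**Figure D2:**
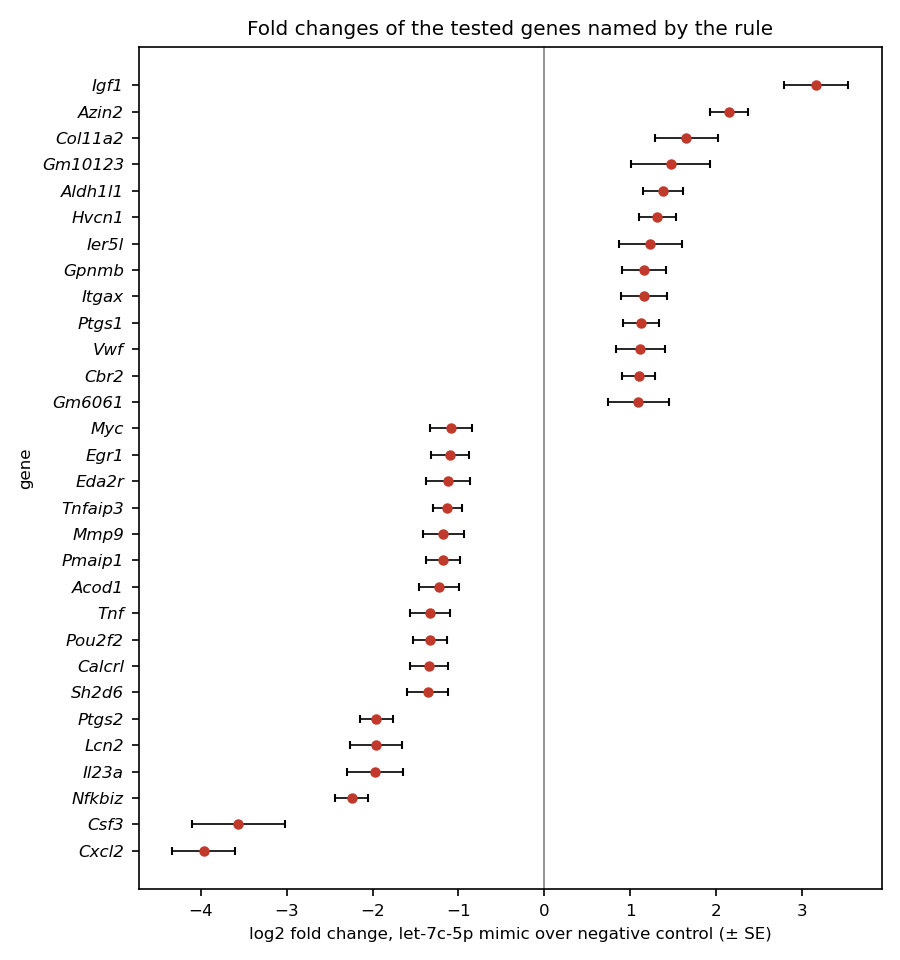
Log2 fold change, let-7c-5p mimic over negative control (horizontal axis, ± SE), of the tested genes named by the rule. Values run from -3.96 for Cxcl2 to 3.16 for Igf1, and since the genes of the table were chosen for a difference, no gene lies near 0.

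Gm10123 (ENSMUSG00000062933) and Gm6061 (ENSMUSG00000093392) had log2 fold changes of 1.47 ± 0.46 and 1.09 ± 0.35, but their values are uncertain. Their annotated transcripts were 99.8% identical over 490 bases, and that of Gm6061 was 98.8% identical to Ppia, so reads of these genes cannot be assigned with certainty. Rpl17 (ENSMUSG00000062328), at 1.09 ± 0.46, had 23 other genes with a transcript at least 95% identical over at least 300 bases. The groups overlapped in Gm6061 and Rpl17. The Rpl17 call was lost under 10 alternative settings, and that of Gm6061 with column totals (0.58), by the exact permutation test (0.91) and without control replicate 2 (0.86). Gm10123 was not called by the exact permutation test (1.23). Gm10123 and Rpl17 together held 29.0% to 35.3% of the counts in the control libraries and 47.5% to 71.2% in the let-7c-5p libraries.

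Over the whole table, 149 genes passed the filter and 148 were called by edgeR, 76 higher and 72 lower. The exception was Muc19 (adjusted p = 0.053). In the deposited counts, without scaling, the groups did not overlap in 95 of the tested genes (63.8%, against 1.59% by chance). However, the genes had been chosen for a difference between these groups, so none of these numbers is independent evidence. The balance of directions depended on scaling: 51.4% of the calls were higher with TMM and with DESeq2 size factors in edgeR, 28.7% with column totals (29 higher and 72 lower, median shift -0.36) and 61.1% with column totals without Gm10123, Gm6061 and Rpl17 (77 and 49, median shift 0.42). The DESeq2 Wald test, which also took in the genes below the filter, gave 40.5% (96 and 141, median shift -0.24). No called gene changed sign under these settings, which the selection for differences of about 2-fold or more made unlikely. Without let-7c-5p replicate 5 and control replicate 1, the libraries farthest from their groups, 77 genes were higher and 81 lower. Spearman correlations between libraries were 0.78 to 0.93 within a group and 0.47 to 0.75 between groups. They were computed on the selected genes, so they cannot show that the libraries separate by group.

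The genes also differed in base composition. The median GC content of the longest transcript was 55.2% in the 74 higher genes with a matched ID and 42.5% in the 70 lower ones (permutation test, two-sided, p = 1e-05, the smallest the resamples can give). The 13 lower genes of the fixed lists had a median of 51.0%, and the 57 other lower genes 41.8%. The groups overlapped in 0 of these 13 list genes and in 33 of the 57 others. This contrast was tried after a first comparison was seen and is restricted to lower genes of a selected table, so it decides nothing. Count level, which also affects overlap, was not matched. Transcript length differed between the directions as well, with a median of 2646.5 bases in the higher and 3835 in the lower genes (permutation test, p = 0.0046).

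**Figure D3:**
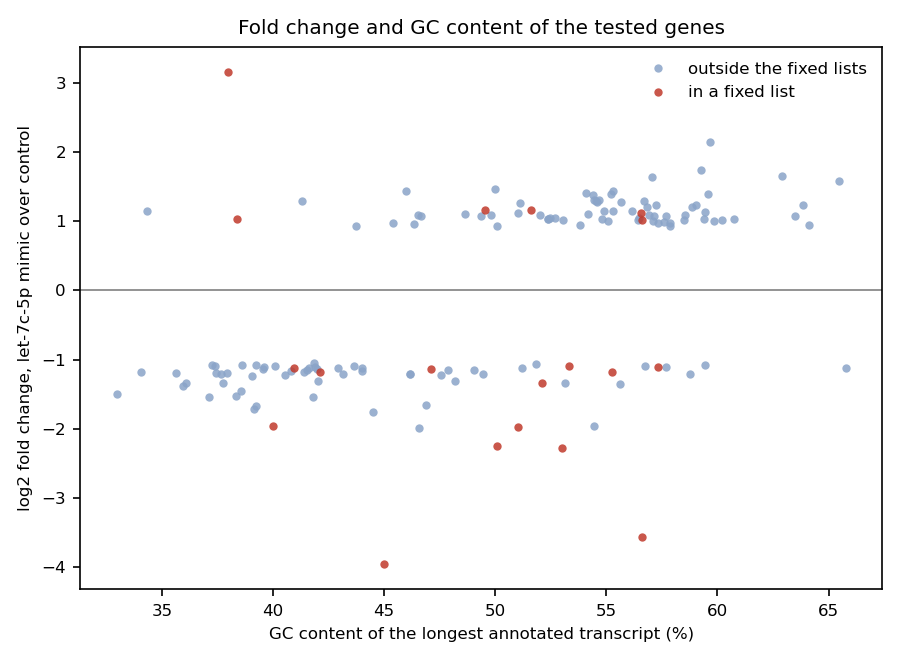
Log2 fold change (vertical axis) against GC content in percent (horizontal axis) of the tested genes with a matched ID. Each point is a gene, red for members of the fixed lists; medians are 55.2% for higher and 42.5% for lower genes, and the empty band around 0 comes from the selection of genes.

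Sites for the let-7 seed were compared between the directions. Of the lower tested genes with an annotated 3′ UTR, 2 of 52 (3.85%) had a 7mer-m8 or 8mer site, Pou2f2 and Tnfaip3. Of the higher ones, 5 of 60 (8.33%) did, among them Igf1. The shares did not differ by more than chance (Fisher's exact test, two-sided, p = 0.45). The median log2 fold change of the 7 genes with a site lay 0.05 above that of 56 genes without even a 6-base match (permutation test, p = 0.66). With no gene of the table near 0, both medians, 1.04 and 0.99, mostly reflect that more genes of each set were higher. This difference therefore does not measure repression, and genes lowered by clearly less than 2-fold are not in the table.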

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

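The tests of GC content in list genes, in higher genes and in lower genes outside the lists, and those of shared reads, were chosen after their results or the counts behind them had been seen. Among 64 groups of libraries, 7 had 1 library far from the others, where about 3.2 are given by chance. In let-7c-5p replicate 4, Cxcl2 had 455 counts (75 to 163 in the other libraries of its group), Ptgs2 409 (219 to 255) and Lcn2 196 (48 to 81). In let-7c-5p replicate 5, Col11a2 had 336 counts (96 to 149), Egr1 1048 (759 to 819) and Ier5l 131 (47 to 71). In control replicate 1, Csf3 had 53 counts (19 to 24).

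Lower genes were GC-poor and higher genes GC-rich. Whether a linear GC trend was the whole cause for the list genes as a set is not decided. The median log2 fold change of all 19 tested list genes, whatever their direction, was -1.13, against 0.96 in the 125 genes outside the lists. With that trend removed, the list median still lay -1.14 from the other (permutation p = 3.5e-04, genes taken as independent). As no gene of the table lies near 0, such a median mostly follows the direction of the majority. Of the list genes 13 of 19 were lower, and of the others 57 of 125. Single genes are not decided by it either. Of 9 versions of this comparison, 8, this one included, were tried after the first, which gave -0.13 (permutation p = 0.072) for the 13 lower list genes against other lower genes of like GC; versions restricted to lower genes decide nothing, since their outcome follows from the selection. For the 57 other lower genes GC may contribute: deviations of libraries from their own group followed GC, with an absolute Spearman rho of up to 0.576 across genes, which are not independent replicates (95th percentile of shuffled GC 0.362; p = 1e-04, the smallest the shuffles can give), although this does not show that GC made the difference between the groups. For the higher genes the largest rho was 0.269, below the 95th percentile of 0.319 (p = 0.16) and above the shuffled median of 0.204, so it does not decide, and an effect of the mimic stays open throughout.

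Gm10123 and Rpl17 took a large share of the counts, and both varied between replicates, as did Gm6061. For Gm10123 and Gm6061 the counts moved together over the 9 libraries (Spearman's rho 0.967, permutation p = 1.6e-04, adjusted p = 4.8e-04 over 3 relations). Pearson's r was 0.990 (permutation p = 7.0e-05), and 0.937 without let-7c-5p replicates 1 and 5. These values pool both groups, and both genes are in a table chosen for a group difference, so part of the relation follows from the selection. Within the let-7c-5p group, replicates 1 and 5 were the highest in both genes. Both genes may count reads of one source such as Ppia, whose own counts were not analysed here. Shared reads between Gm10123 and Rpl17 are argued against, since their transcripts had no alignment; no relation of their counts was detected, with a rho of 0.367 (permutation p = 0.34; r = 0.153, p = 0.70). Whether the mimic raised any transcript behind these reads stays open.

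The real grouping called 148 genes, and 1 of 100 drawn splits of the libraries, the real one, gave as many; the highest other split gave 58. Chance cannot be judged from this, because the genes were chosen on the real grouping.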

How the results depend on the processing

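The settings without both outlying libraries and with column totals lacking Gm10123, Gm6061 and Rpl17, and all list tests, were chosen after seeing the data. Against 148 calls (76 higher, 72 lower), no filter gave 311 calls, 170 higher and 141 lower, since it tests more genes. DESeq2, which also took in the genes below the filter, gave 237 calls with 141 lower, as many lower as without the filter. It called 96 higher, against 170 without the filter, with a median shift of -0.24. The cause of that gap was not tested. Column totals left 29 higher, against 77 with Gm10123, Gm6061 and Rpl17 taken out of the totals, so these genes' share of the counts made that loss. The other settings stayed within 1.5 times: 49 lower with column totals lacking the 3 genes, 158 without both libraries, and 131 to 164 leaving out each library (65 to 82 higher, 66 to 82 lower). No gene called in the main test changed sign, but each had been chosen for a difference of about 2-fold or more on these libraries. The rule for naming the largest changes also required the same direction in each leave-one-out fit. Kept signs and calls, here and for the single genes below, are therefore little evidence of robustness. The replicate number as a block gave 144 calls; same-numbered libraries did not deviate together (0 of 4 correlated best with their own number). Of the 3 lists past the threshold, 0 were with an estimated correlation (adjusted p = 0.12 each; 0 also at an unadjusted p under 0.05); the block ended the lysosome call (adjusted p = 0.058). The first principal component held 72.5% of the variance, and 68.0% on ranks, in genes chosen for a difference between the groups. For single genes, 673 values kept direction and call and 17 kept direction only, among them Rpl17 under 10 settings and Gm6061 without control replicate 2 (0.86) or with column totals (0.58); Gm10123 was not called by the exact permutation test. Seed sites gave no call under any setting run. Housekeeping scaling and the list test at 5 members were not run. Low counts limit 162 untested genes, and sequencing depth is unknown.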

Other observations

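The tests of gene classes were chosen after the counts had been seen; the comparison of seed sites and the GC prediction for zinc finger genes were written before their results. Of the 311 genes, 193 were protein coding, 121 with a higher and 72 with a lower mean after let-7c-5p. Genes annotated as awaiting experimental evidence (TEC) went the other way: 20 of 23 had a lower mean (Fisher's exact test against the rest of the table, adjusted p = 2.4e-04 over 7 classes). All 5 small nucleolar RNA genes had a lower mean too (adjusted p = 0.043), and 0 of them passed the filter. Median GC was 44.0% in the TEC genes and 44.6% in the small nucleolar RNA genes, against 52.5% in the protein coding genes. Processed transcripts (45.1%) and lincRNAs (46.3%) had nearly as low a GC, and 50% and 43.8% of them were lower (adjusted p = 1 each). With 10 and 16 genes, these classes cannot decide whether low GC tracked direction. The table holds selected genes, so these shares describe the table.

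All 10 genes with a Zfp (zinc finger protein) symbol had a lower mean, against 43.5% of the 301 other genes (Fisher's exact p = 3.1e-04, on a group noticed in the data), and the 6 tested were called. A candidate explanation is again GC content: their median GC lay -4.26 percentage points from that of the other lower genes, at 39.6% against 43.8%, and the groups overlapped in 80% of them against 55.6%. An effect of let-7c-5p on these genes remains open.

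The hypothesis that let-7c-5p directly represses the lower genes through seed sites predicted more sites among them. The share was smaller, not larger, 3.85% against 8.33% (Fisher's exact p = 0.447), and above the median 3′ UTR length it was 2 of 35 against 4 of 21 (p = 0.18). With 7 genes carrying a site the test cannot decide. The share of tested lower genes with a site, 2 of 52, has an exact 95% interval of 0.469% to 13.2%, which treats selected genes as a random draw. Among all lower genes of the table with an annotated 3′ UTR, 4 of 71 carried such a site, against 12 of 117 higher ones (Fisher's exact p = 0.42). Indirect effects and other kinds of site were not tested.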
